A study of Homo sapiens with 2 samples.

How the data were processed

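Single cells of 2 sorted groups, double positive and GFP single positive, were captured on a Fluidigm C1 chip on day 33, and their polyA RNA was sequenced, per the labels' protocols. The submitters' processing notes name FastQC, Trim Galore, STAR 2.5.2b, limma 3.38.3 and the genome build GRCh38, with no role or order. How reads were counted and which cells were removed as outliers is not given in the sources used here. The deposited table holds whole-number counts per gene and cell, and the authors' values were used without normalization. Every gene in it summed to at least 398 counts and every cell had at least 1800 genes with a count, so genes and cells below such levels were not analysed here. A second deposited file pairs each of the 398 cells with an index sequence.

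The number of value columns not used was 0. Gene symbols and coordinates were taken from GENCODE 29 on GRCh38, in which 12251 of the 12276 identifiers were found and 25 were not. Levels of 16 sex-linked genes were left out of all printed results. No map from cells to sorted groups was used, so the planned comparison between groups gave way to its stated fallback, in which all cells form 1 pooled sample without a test. Chip position and SFTPC level were never used to assign a group. No doublet caller was run, and chambers holding 2 cells remain possible.

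Summed CPM is the sum of a gene's counts over cells per 1000000 summed counts, and cell CPM uses the total of that cell. Shares of cells are given with exact 95% binomial intervals and sums with exact Poisson intervals. A cell was called high at 100 CPM and 5 counts, a rule chosen after seeing the data, because 1 count passed 100 CPM in shallow cells. Cells were thinned without replacement to the 10th percentile of totals (35438 counts, 40 cells left out) and the 25th percentile (192547 counts, 100 cells left out).

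Before the data were examined, 36 gene lists, 12 sets of cell type markers and the rule for named genes were fixed. The rule named SFTPC and NKX2-1, the 2 members of each list with the highest mean CPM and the 10 genes with the highest mean CPM. Its part on differences between groups did not apply, and some genes it named are not reported here. Other named genes, such as TF in a cluster, PRSS1, SPINK1, CEL and the leading genes of clusters, were chosen after their values were seen, and SFTPB, SCGB3A2, MKI67, SOX2 and SOX9 were paired with other genes after seeing the data. Expected numbers of cells high for both genes of a pair were summed over chip columns.

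The covariation of lists was added after seeing the data. A first version used unthinned cells, with 16 of 30 lists at or above the 99th percentile, and the thinned version was then made the main one so that all cells had the same total. Genes with at least 5 CPM were ranked within chip columns, and random lists were drawn from 20 bins of expression. A ranking of 10623 single genes by their correlation with SFTPC was also computed and set aside, with a largest value of 0.251. For list pairs, 120 correlations were computed, each against 1000 random pairs. Clusters used log-normalised counts scaled to 10000 per cell, 1500 variable genes, 15 principal components, 10 neighbours and Leiden resolution 0.8, with scanpy 1.11.5 and leidenalg 0.10.2. Scaling to 1000000 was tried first and set aside because its clusters followed chip columns. Leading genes were ranked by the ratio of mean CPM plus 20 among genes with a count in at least 50% of the cluster's cells.

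The covariation step was tested on simulated counts of 10638 genes in 298 cells. Of 100 lists with no shared signal, 2 reached the 99th percentile. A low number was set by the design, since these lists and their random lists came from the same independently simulated genes. Shared effects of cell quality or transfer were not simulated there. Of 10 lists of 20 genes raised in 30% of cells, 1 did at 2-fold, 6 at 4-fold and 10 at 16-fold, so weak programmes can be missed. The transfer estimate returned 0.051% for a simulated rate of 0.05%. That simulation gave every other cell of the chip column the same rate. Low counts then appeared in 69.9% of those cells, against 13.9% in the data, so uneven transfer was not covered. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9. Alternatives for thinning, detection, weighting, cell quality, clustering and ranks were recomputed.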

Results

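The study measured polyA RNA of single lung epithelial cells made from BU3-NGST, a human induced pluripotent stem cell line that carries a GFP reporter at NKX2-1 and a tdTomato reporter at SFTPC. NKX2-1 encodes the transcription factor that marks lung and thyroid epithelium, and SFTPC encodes surfactant protein C of alveolar type 2 cells. Cells were first sorted for GFP on day 15 and then grown in Matrigel in a distal lung medium that combined a WNT activator (CHIR), KGF, a glucocorticoid, cyclic AMP and a phosphodiesterase inhibitor (IBMX). On day 33, cells positive for both reporters and cells positive for GFP alone were sorted and captured on a Fluidigm C1 chip, a microfluidic device that holds 1 cell per chamber. The labels describe 1 sample of each of these 2 sorted groups. The count table names each cell by its chip column and row, and no cell was assigned to a sorted group here. All 398 cells were therefore treated as 1 pooled sample, and the groups were not compared.

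The 398 cells held 150380715 counts over 12276 genes. The total per cell ranged from 9373 to 1647904 with a median of 344925, and the number of genes with a count ranged from 1800 to 5438 with a median of 3130. Mitochondrial genes took a median of 12.8% of the counts of a cell, with a range of 2.87% to 37%, and 67 cells lay above 20%. The cells came from 14 chip columns of 14 to 36 cells, whose median totals ran from 238907 to 759326. There were no replicates. Intervals are exact 95% Poisson or Clopper-Pearson binomial intervals and cover counting error only. The Poisson intervals treat counts as independent, which was not checked. The sources used here do not say whether reads were collapsed to molecules.

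The first question was how strongly the genes behind both reporters were expressed in the sorted cells. SFTPC (ENSG00000168484, GRCh38 chromosome 8, 22156913 to 22164479, plus strand) reached 295.5 CPM (counts per 1000000 of the summed counts), with an interval of 292.8 to 298.3. A count of SFTPC was present in 201 of the 398 cells (50.5%, interval 45.5% to 55.5%). A level of at least 100 CPM with at least 5 counts, called high from here on, was found in 74 cells (18.6%, interval 14.9% to 22.8%). The 20 highest cells held 72.8% of all SFTPC counts. NKX2-1 (ENSG00000136352, chromosome 14, 36516392 to 36521149, minus strand) reached 86.17 CPM (interval 84.69 to 87.66), with a count in 252 cells (63.3%, interval 58.4% to 68.1%) and a high level in 77 cells (19.3%, interval 15.6% to 23.6%). The SFTPC share depended on depth. After each cell was thinned to 35438 counts, 124 of the 358 cells deep enough had an SFTPC count (34.6%, interval 29.7% to 39.8%). Genes that were high in a single cell had low counts more often in other cells of its chip column than elsewhere, so a single count was weak evidence of expression.

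**Figure D1:**
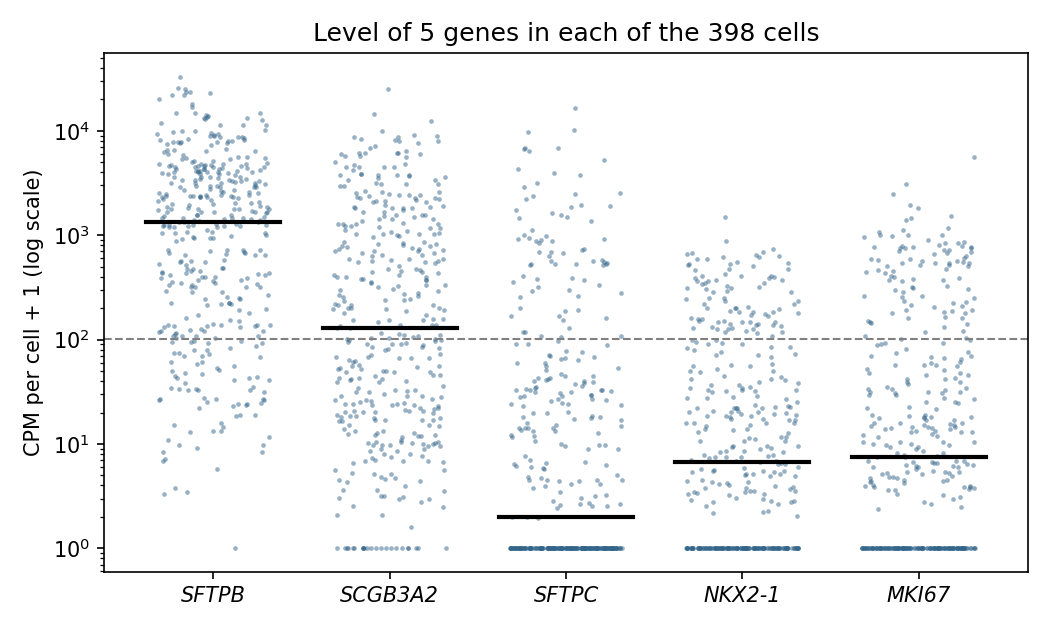
Level of SFTPB, SCGB3A2, SFTPC, NKX2-1 and MKI67 in each of the 398 cells, as CPM plus 1 on a log axis, with 1 point per cell, the median as a black bar and the level of 100 CPM as a dashed line. SFTPB was high in 320 cells and SFTPC in 74 cells.

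**Figure D2:**
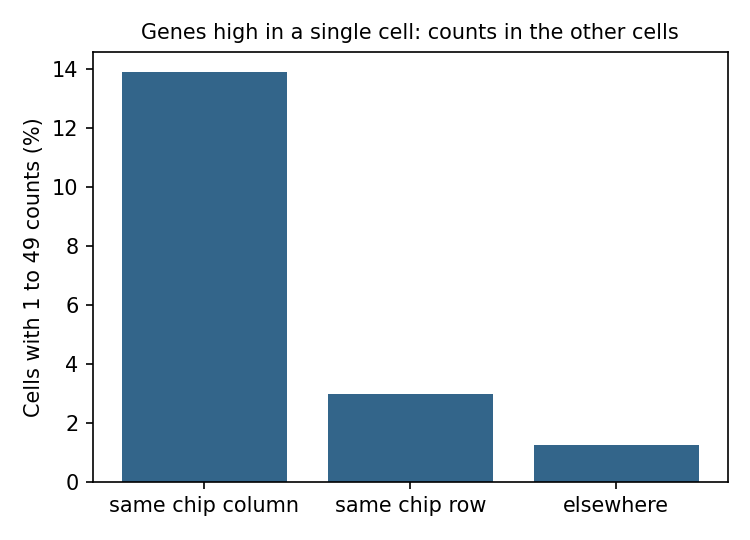
Share of other cells with 1 to 49 counts (percent, bars) of 276 genes that had at least 500 counts in a single cell and under 50 in every other cell, by position on the chip. The share was 13.9% in the same chip column, 2.97% in the same row and 1.25% elsewhere.

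SFTPC-high cells were unevenly spread over the chip. A chip column of 29 cells held 0 of them, which allows up to 11.9%, and a column of 36 cells held 18 (50%, interval 32.9% to 67.1%). These were the extremes of 14 columns, and the median column had 14.7%. Most SFTPC-high cells lay in columns c11 to c20, although columns c01 to c10 held more of the cells. This split was seen after the fact and not tested. Of the 74 SFTPC-high cells, 12 were also NKX2-1-high, against 13.8 expected from the product of both shares within each chip column. No test was made of these numbers, and depth per cell was not allowed for in the expected ones. The number that were also high for SFTPB, which encodes surfactant protein B, was 70 against 63.2 expected, or 59.5 from the shares over all cells. For the airway secretory gene SCGB3A2 it was 43 against 36.6, and for the proliferation gene MKI67 it was 21 against 16.2. An uneven spread was not particular to SFTPC. The share of high cells in a chip column ran from 0% to 54.5% for MKI67 and from 21.4% to 75% for SCGB3A2. It ran less widely for NKX2-1 (9.09% to 35.3%) and SFTPB (65.5% to 100%).

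Surfactant and distal lung genes were detected at very different levels. Of the 22 fixed genes of the alveolar type 2 list, 17 were in the table and 4 of them were high in at least 20% of cells. Genes in the table are called measured from here on, and each summed to at least 398 counts. A gene that is absent may therefore have been low, and list medians cover measured genes alone. SFTPB led with 3136 CPM, a count in 397 cells and a high level in 320 (80.4%, interval 76.2% to 84.2%), followed by MUC1 with 481.9 CPM and a high level in 183 cells. Among lung epithelial transcription factors, 3 of the 13 measured genes were high in at least 20% of cells, and ELF3 (255.7 CPM) and FOXP1 (227.3 CPM) led. In the lung tip progenitor list, 2 of 15 measured genes were, namely the gene for carboxypeptidase M (595.1 CPM) and HMGA2 (414.8 CPM), a chromatin protein of embryonic cells. SOX2 and SOX9, transcription factors of the proximal and distal airway bud, were both high in 13 cells against 6.3 expected within chip columns. No test was made, and neither depth per cell nor chambers with 2 cells were allowed for.

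Markers of other lung cell types were mixed. SCGB3A2 reached 1077 CPM and was high in 204 cells (51.3%, interval 46.2% to 56.3%), and WFDC2, another gene of the airway secretory list, reached 898.7 CPM and was high in 288 cells. That list had 6 of its 16 genes in the table. In the alveolar type 1 list, IGFBP2 (446.5 CPM) and LMO7 (184.3 CPM) were the members with the highest mean level, and the median of its 11 measured genes was 22.2 CPM. Basal, ciliated and neuroendocrine lists each had no gene that was high in 20% of cells. Their leading members were ITGA6 (18.51 CPM) and KRT15 (12.24 CPM), PIFO (32.44 CPM) and TPPP3 (12.99 CPM), and SCG5 (19.08 CPM), in that order.

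Levels of markers of other lineages varied by list. The median was 294 CPM over 2 measured gastrointestinal genes and 186 CPM over 5 mesenchymal genes. It was 11.8 CPM over 7 hepatic genes and also over 2 thyroid genes. TF, the transferrin gene of the hepatic list, reached 226.5 CPM and was high in 82 cells, while TTR (38.68 CPM) was high in 11 cells. TFF3, a mucosal peptide gene of the gastrointestinal list, reached 567 CPM and was high in 193 cells, against 21.42 CPM for VIL1. The thyroid list was led by HHEX (19.93 CPM) and TG (3.624 CPM). PECAM1 (3.132 CPM) was the single measured gene of the endothelial and blood list. Of the pluripotency list, SOX2 (88.74 CPM) and DNMT3B (8.385 CPM) were measured, and the absence of its other genes can mean a low level. VIM, which encodes the intermediate filament vimentin, reached 1792 CPM and FN1 366.8 CPM in the mesenchymal list, and the epithelial keratins KRT18 and KRT19 reached 1053 CPM and 994.8 CPM.

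Of the cell cycle lists, 4 of 19 measured G2/M genes and 2 of 18 S phase genes were high in at least 20% of cells. MKI67 reached 180 CPM and TOP2A, the DNA topoisomerase of dividing cells, 345.6 CPM. A count of either gene was found in 344 cells (86.4%, interval 82.7% to 89.6%), a share that was 59.2% (interval 53.9% to 64.4%) after thinning to 35438 counts. Either gene was high in 152 cells (38.2%, interval 33.4% to 43.2%) and both were in 59 cells (14.8%, interval 11.5% to 18.7%). CENPF (274.6 CPM) was the other leading G2/M gene, and MCM7 (197.7 CPM) and RRM1 (179.1 CPM) led the S phase list.

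Among signalling and metabolic lists, leading members were SCD (1565 CPM) and PLIN2 (282.1 CPM) for fatty acid and phospholipid synthesis and ENO1 (4058 CPM) and PGK1 (2140 CPM) for hypoxia and glycolysis. DUSP6 (448.4 CPM) and PHLDA1 (357.5 CPM) led the FGF response list, CTGF (617 CPM) and CYR61 (550.1 CPM) the YAP target list, HES1 (493.1 CPM) and HES6 (135.1 CPM) the Notch list, and TNFRSF19 (157.9 CPM) and NKD1 (102.7 CPM) the WNT target list. ID3 (235.4 CPM) and ID2 (137.9 CPM) led the BMP and TGF-beta response list. ERRFI1 (469.5 CPM) and DUSP1 (453 CPM) led the glucocorticoid list, and DUSP1 and AREG (88.44 CPM) the cyclic AMP list.

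Stress, immune and housekeeping lists were led as follows. KLF6 (1089 CPM) and EGR1 (716.7 CPM) led the dissociation stress list, 10 of whose 14 genes were high in at least 20% of cells. HSP90B1 (1433 CPM) and HSPA5 (779.6 CPM), endoplasmic reticulum chaperones, led the unfolded protein response list. NFKBIA (279.8 CPM) and CXCL2 (304.7 CPM) led the chemokine list, B2M (218.1 CPM) antigen presentation, and IFITM3 (152.8 CPM) the interferon response. CD63 (1009 CPM) and NPC2 (661.4 CPM) led the lysosome list, and COX4I1 (604.8 CPM) and COX7C (539.7 CPM) nuclear oxidative phosphorylation. The 10 genes with the highest mean CPM included MT-RNR2, MT-ND4, MT-ATP6, MALAT1, MT-CO2, RPS18, MT-CYB, RPS14 and PRSS2. PRSS2, a trypsinogen gene with near-identical copies, reached 8068.14 CPM, a level that is uncertain because reads can be split between copies.

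Genes of the same list often rose and fell together from cell to cell. Covariation was the mean pairwise rank correlation of a list's genes within chip columns, over 298 cells thinned to 192547 counts, set against 10000 random lists matched on expression. Of the 28 lists with at least 5 genes at 5 CPM or more in the thinned counts, 16 lay at or above the 99th percentile. Lists drawn like the random ones would give 0.28. The mean correlation was 0.252 for G2/M genes, 0.153 for S phase genes, 0.138 for hypoxia and glycolysis genes, 0.0969 for hepatic genes and 0.0895 for dissociation stress genes. It was 0.0821 for cholesterol synthesis, 0.0759 for YAP target, 0.0721 for chemokine and 0.0559 for alveolar type 2 genes. Random medians of these lists were 0.00628 to 0.0204. The hepatic value rested on 6 genes, of which TF was high in 82 of the 398 cells and the others in 11 (TTR) or fewer. The mitochondrial list had 0.423 and the ribosomal list 0.104, but few genes match their level. Cells are not replicates, so these percentiles describe this pool alone.

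**Figure D3:**
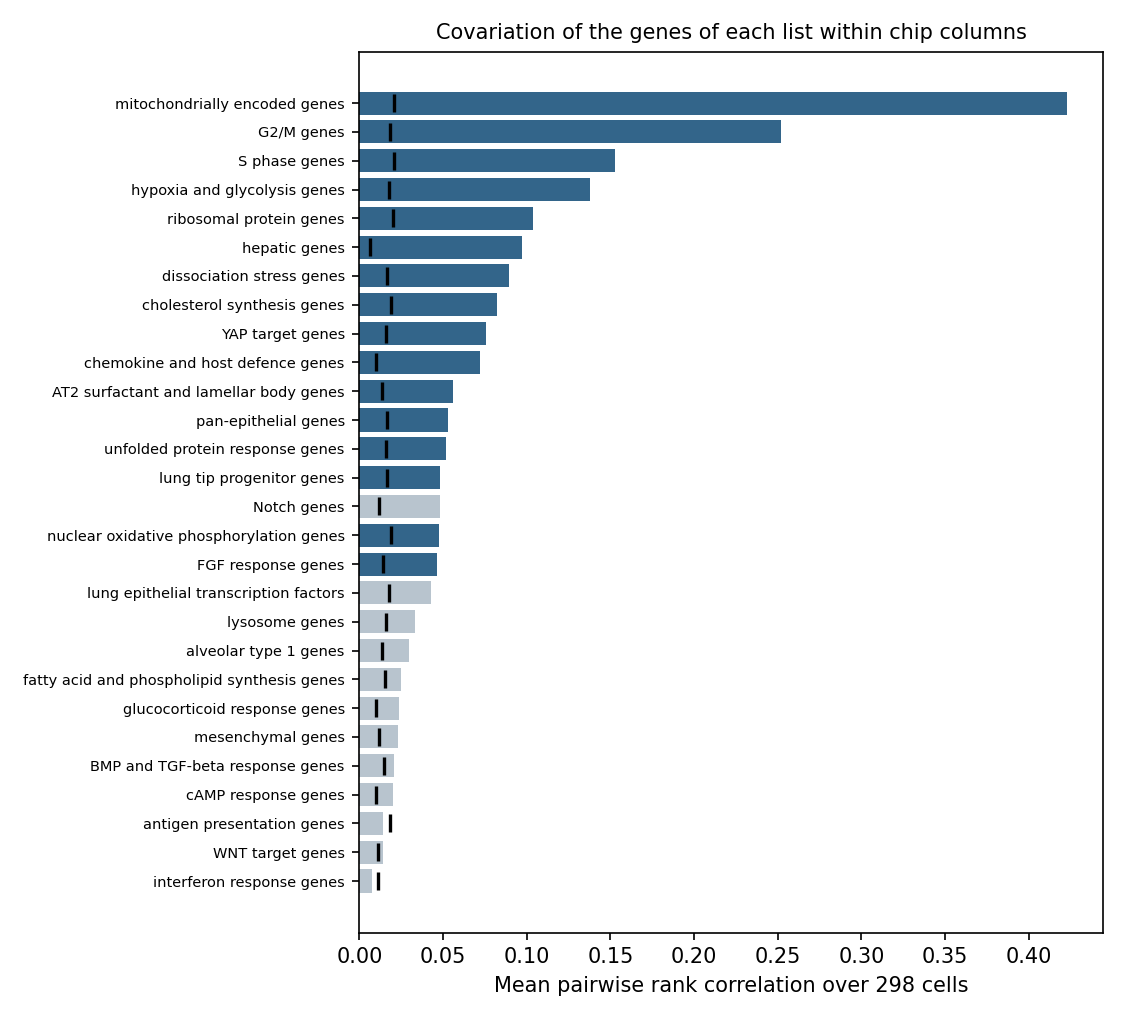
Mean pairwise rank correlation of the genes of each of 28 lists over 298 cells, within chip columns (bars), with the median of 10000 matched random lists (black ticks). Dark bars mark the 16 lists at or above the 99th percentile, led by the mitochondrial list at 0.423 and G2/M genes at 0.252.

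SFTPC itself followed the lists weakly. Its rank correlation with the mean rank of the alveolar type 2 list was 0.186, at the 99.2 percentile of random lists and positive in 11 of 14 chip columns. This was the only one of 28 lists at or above the 99th percentile, and it fell below that in 4 of 6 alternative settings, to the 97.2 percentile without thinning. With ranks over all cells, which keep differences between chip columns, the correlation was 0.236 (99.7 percentile). SFTPC had a correlation of -0.13 with nuclear oxidative phosphorylation genes (0.7 percentile) and of 0.00973 with G2/M genes (31.7 percentile).

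Clustering gave 8 groups of 98, 80, 72, 37, 35, 34, 34 and 8 cells. Cluster 1, with 98 cells, was led by IGFBP3, EGLN3, MRPS6, WSB1 and TF and met no set of cell type markers. Clusters 2 and 6 were cycling-like by the rule of at least 3 markers raised at least 2-fold. Cluster 2 was led by TJP1 and HMGA2 with CCNB1 among its 10 leading genes, whereas cluster 6 was led by TEX261 and ASXL1 and had 0 cycling markers among them. The other clusters stayed unnamed. Clusters 4 and 8 were shallow, with median totals of 111972 and 113384 counts against 344925 over all cells. Clusters that shallow were given no name by the rule. In cluster 5, 42.9% of the cells came from 1 chip column. Membership was unstable, with an adjusted mutual information of 0.3 to 0.686 between the main clusters and those of 5 settings fixed in advance, where 1 is identity. In the settings not fixed in advance it was lower, at 0.247 after centring within chip columns, 0.166 with counts scaled to 1000000 and 0.0409 with low counts set to 0.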

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

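The values in this part were looked up after the data were seen. The pairing of cells with index sequences, which no result of the report uses, held 39 cells whose index differed by 1 base from the most frequent index of their chip column. In 8 of these cells the index had an unread base. Their median total was 348484 counts, against 344729 in the other cells, and their median number of genes 2919 against 3159. No explanation was tested.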

How the results depend on the processing

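Alternatives to the shares of cells by thinning and by 5 counts, and to clustering by resolution, variable genes and cell cycle genes, were planned. All others were chosen after seeing the data. The share of cells with SFTPC counts was 50.5% as deposited, 34.6% and 40.9% after thinning to the 10th and 25th percentile, 32.4% at 5 counts and 18.6% at 100 CPM. The share with MKI67 or TOP2A counts was 86.4%, then 59.2%, 80.5% and 38.2% under the same thinnings and 100 CPM. Summed SFTPC of 295.5 CPM became 349.2 with cells weighted equally, 358.7 after thinning, 350.2 with the 10 most abundant genes out of the totals and 270.9 without cells of doubtful quality. The cause of these shifts was not tested beyond depth and weighting. The 8 clusters became 5 at resolution 0.5 and 8 to 10 under the other 7 settings. With low counts set to 0, the adjusted mutual information with the main clusters was 0.0409, so cluster membership should not be relied on. The count of lists at or above the 99th percentile was 15 or 16 in every setting run. None of these settings, which also served the list correlations below, set low counts to 0. Whether low counts within chip columns shape the covariation was therefore not tested. The correlation of SFTPC with the alveolar type 2 list stayed positive but left the 99th percentile unthinned (0.163), at 20 CPM (0.155), without cells of doubtful quality (0.167) and with the most abundant genes out of the totals (0.181). It stayed above the 99th percentile after thinning to the 10th percentile (0.176) and with ranks over all cells (0.236). The cause was not tested. The correlations of the FGF and YAP lists (0.425) and of the S phase and hypoxia lists (-0.205) stayed within 1.5 times in all 6 settings run. Settings fixed in advance for the SFTPC ratio, genes 2-fold apart and list medians between groups were not run, since no cells were assigned to groups. No paired analysis was possible because each group has 1 sample and the result comes from no test.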

Other observations

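FGF response genes and YAP target genes rose and fell together. The correlation of their mean ranks was 0.425, against a median of 0.145 for random pairs, and was positive in 14 of 14 chip columns. Lung tip progenitor genes and FGF response genes had 0.338 (99.7 percentile, positive in 12 of 14 columns) after 2 shared genes were left out. Dissociation stress genes had 0.296 with FGF response genes (98.3 percentile, 1 shared gene left out) and 0.287 with YAP target genes (97.7 percentile), both under the 99th percentile. YAP target genes lay as high with alveolar type 2 genes (98.5 percentile) and with chemokine genes (97.7 percentile). S phase genes and hypoxia and glycolysis genes had -0.205, against a random median of 0.23 (0 percentile), negative in 11 of 14 columns. The other cell cycle list, G2/M genes, had -0.0425 with hypoxia and glycolysis genes, negative in 7 of 14 columns. This was nearer to no correlation but also at the 0 percentile, against a random median of 0.229. These pairs were picked after the data were seen from 120 pairs of the 16 lists with high covariation. Of the 120, 2 lay at or above the 99th percentile and 33 at or under the 1st. For lists like the random ones, 1.2 would be expected in each. The random lists were not chosen for covariation, so 1.2 is a rough guide at most. Most of the 33 involved the mitochondrial or ribosomal list, whose level few genes match. Random pairs were themselves positively correlated and CPM is a share of a fixed total, so a low percentile is weaker evidence than a high one.

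All tests below were chosen after the result was seen. For 276 genes with at least 500 counts in a single cell and under 50 in every other, low counts were found in 13.9% of the other cells of the same chip column, 2.97% of cells in the same row and 1.25% elsewhere. The share in the column was 11.2 times that elsewhere, which argues against free RNA shared by all cells as the whole source. Reads of other cells of the same chip column may be the source, at a median of 0.0555% of the high cell's reads per other cell. Other thresholds gave 12.9%, 19.3% and 13% in the column. No biological explanation was tested.

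The spread of SFTPC-high cells over chip columns was recounted with these reads allowed for, and the extremes stayed apart. Such a recount only removes cells and the lowest column already held 0, so the spread could not widen. Of the 74 cells, 61 lay above 10 times the transferred count (82.4%, interval 71.8% to 90.3%). That share was the test used first, and it was replaced because its interval spanned the limit set for it. Counting those 61 cells alone, the highest column went from 18 to 12 of its 36 cells (50% to 33.3%). Its lower bound was then 18.6%, against an upper bound of 11.9% in the lowest column. This cannot decide whether transfer was the whole cause, since the rate came from genes with under 50 counts in every other cell. Larger transfers were left out by that choice. After thinning, the lower bound of the highest column was 26.8% against an upper bound of 14.2% in the lowest, which argues against depth. Columns were picked as extremes of 14, which these intervals do not cover. The sorted group loaded into each chip column stays a possible explanation that cannot be told apart here, since 0 of the 398 cells were assigned to a sorted group.

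PRSS2 was high in 88.4% of cells. Acinar-like pancreatic cells are unlikely as the whole source. Of 18 acinar markers, 3 were in the table and 0 reached 806.8 CPM, 10 times under the PRSS2 level. These 3 were PRSS1 at 624 CPM, the closest to that limit, SPINK1 at 86.8 CPM and CEL at 2.68 CPM. The cells were sorted for the NKX2-1 reporter, but whether this gate removed acinar-like cells was not tested. Reads of other cells stay open for part of the pattern, since 61.9% of PRSS2-high cells (interval 56.6% to 67%) lay above 10 times the transferred count. Reads shared with PRSS1, at 624 CPM, or PRSS3 cannot be told apart from PRSS2 by these counts. The level of PRSS1 as an acinar marker is therefore uncertain as well. No biological explanation other than acinar-like cells was tested.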
